A study of Mus musculus with 9 samples.

How the data were processed

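The series holds single-cell RNA-seq of central amygdala cells that were microdissected, dissociated and pooled over acute slices of wild-type B6 mice, per the labels. It has 9 samples of 1 group, with 3 animal numbers crossed with 3 date fields. The authors deposited raw counts per gene symbol and cell, in a table of 22601 genes (22299 with a count) and 91 ERCC spike-ins, with a table that gives the animal number and date field of each cell. The genome build was NCBIM37 and a tool named was Seurat, per the submitters' processing notes. The aligner, the gene annotation, the strand of counting, the treatment of reads that match several genes and the use of molecular identifiers are not given in the sources used here. Whether the counts hold PCR copies is therefore not known, and counting intervals cover counting error only.

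Whether the 9 samples come from separate animals is not given in the sources used here, so the p-values measure only the spread between these samples. The samples held 95, 93, 93, 95, 95, 93, 85, 87 and 93 cells, of which 95, 92, 93, 95, 93, 90, 82, 86 and 84 were classed as inhibitory neurons. The median gene counts per cell, over all cells of a sample, were 120451, 113115, 121503, 152952, 227570, 141659, 101829, 96558 and 107625. A cell was positive for a gene with at least 1 count per 10000 of its gene counts, spike-ins left out. Inhibitory neurons were cells positive for Gad1, Gad2 or Slc32a1 and for neither Slc17a7 nor Slc17a6, 810 in all. The other 19 cells were left out. No cell was removed for low counts, and 9 of the neurons had under 20000 counts, the lowest 401. No doublet caller was run, and 23 neurons positive for Prkcd and Sst entered neither class of that comparison.

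For each comparison the counts were summed per sample and class, where each class had at least 5 cells, and all 9 samples entered each. The sums were tested with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood test, sample as a block) in R 4.3.3. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are those of the fit with the block and differ from ratios of the mean CPM. Where a class had 0 counts of a gene, the bound uses a floor of 3 counts over the class, and with 1 to 3 counts the ratio of summed counts with its 95% counting interval is given. Gene lists were written before the data were examined and tested with camera of limma 3.58.1 at a correlation of 0.01 and with an estimated correlation. They hold 443 genes, of which 417 were in the table, 10 by an older symbol, and 26 were not used here. Marker pairs and shares were tested by exact two-sided sign-flip permutation over samples, for which 9 samples allow a smallest p of 0.00391. For odds ratios 0.5 was added to each cell of the 2 by 2 table, and 29 transcription factors positive in at least 2% of cells were tested.

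The genes named are up to 12 with the largest fold on each side among those that passed, had a mean of at least 10 CPM and moved the same way in every sample. Up to 2 passing members of each list are added, a number lowered from 4 after the data were seen, with Prkcd, Sst, Crh, Tac2, Nts, Isl1 and Nr2f2 whatever their result. Some genes that met these rules or those for clusters are not used here. Cell type annotation by the submitters was not used here. Clusters are Leiden clusters of log-normalized counts (scanpy 1.11.5, igraph 0.11.9, 2000 variable genes, 30 components, 15 neighbours, resolution 1). Seed 7 was used to thin the counts and to split them at random, not for the clusters. Up to 4 genes are named per cluster, by the ratio of mean CPM to the next cluster, at 20 CPM or more and higher in every sample with at least 5 cells. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and scikit-learn 1.9.0.

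The fits were tested on simulated sums with the library sizes, gene means and dispersions of the real ones. In these, 100 genes were changed 2-fold and 100 changed 4-fold. No cells were drawn, so the simulation leaves out effects of unequal cell numbers. For Prkcd against Sst cells 28% and 45% were recovered with 5 false calls, for Isl1 cells 20% and 53% with 0, and for Nr2f2 cells 14% and 63% with 1, so many changes of 2-fold go unseen. Alternatives planned were median-of-ratios scaling, DESeq2 1.42.0, no filter, no sample block, positive at 1 count or at 3 per 10000, counts thinned to 74000 per cell (733 cells kept), at least 10 cells per class, all cells deposited, each sample left out, and 10 markers in place of 5. Chosen after the data were seen were equal cell numbers per class, sums per animal number or date field, and leaving out cells under 20000 counts, cells positive for Mbp, for Chat, or for at least 4 oligodendrocyte genes. Also chosen then were 10 draws of random classes with the same cell numbers as the real ones. In the random Isl1 classes 999 to 1190 genes had an unadjusted edgeR p under 0.05, of 10951 to 11064 tested. At most 1 of them passed.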

Results

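Single-cell RNA-seq counts were analysed for cells taken from the central amygdala of wild-type B6 mice in 9 samples that form 1 group. The central amygdala is a forebrain nucleus made up largely of GABAergic neurons and takes part in fear, pain and feeding. The study set out to describe the transcriptomes of its inhibitory neurons, and the labels name no treatment, so every comparison is between cells of the same samples. Its cells are commonly sorted by a few classical markers, namely Prkcd (protein kinase C delta), Sst (somatostatin), Crh (corticotropin-releasing hormone), Tac2 (the neurokinin B precursor) and Nts (neurotensin). The samples held 85 to 95 cells each. Their total gene counts were 12593207, 10859073, 12725681, 15956198, 22730327, 14464002, 8576314, 8522750 and 10473459 in samples 1 to 9. The 810 cells classed as inhibitory neurons had a median of 126576 gene counts and 4527.5 detected genes per cell.

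Gad1 and Gad2, which encode the GABA-making enzymes, were positive in 89.6% ± 3.68 and 94.9% ± 1.92 of the inhibitory neurons (mean ± SD over samples, n = 9), where a positive cell had at least 1 count of the gene per 10000 of its gene counts. Slc32a1, the vesicular GABA transporter, was positive in 16.7% ± 5.07. A cell had to be positive for Gad1, Gad2 or Slc32a1 to be classed as inhibitory, so these shares follow in part from that rule. Of the 19 cells left out, 2 were positive for Slc17a7 or Slc17a6, the vesicular glutamate transporters, and 8 had under 20000 counts. Prkcd was positive in 42.5% ± 6.87 of the neurons, Sst in 18.1% ± 6.01, Nts in 14.1% ± 4.77, Tac2 in 13.4% ± 6.76 and Crh in 10.3% ± 3.74. The enkephalin precursor Penk was positive in 77.7% ± 5.85. Calcrl, which encodes the receptor for calcitonin gene-related peptide, was positive in 3.72% ± 2.10, and the dopamine receptor genes Drd1a and Drd2 in 3.44% ± 1.76 and 3.02% ± 2.19. The serotonin receptor gene Htr2a was positive in 1 cell. The transcription factor genes Isl1 and Nr2f2 were positive in 9.30% ± 3.58 and 14.5% ± 4.24. Sst had at least 1 count in 54.8% ± 21.4 of the neurons, although only 18.1% reached the level that makes a cell positive, at a median of 2803 CPM. Among genes of other brain cell types, the oligodendrocyte gene Mbp was positive in 26.0% ± 6.23 of the neurons. The astrocyte gene Aqp4 was positive in 1 cell and the precursor gene Pdgfra in 3 cells. The microglial gene C1qa and the endothelial gene Cldn5 were positive in 0 of 810, which allows a share of up to 0.370% by counting error alone.

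Sst, Crh, Tac2 and Nts were found together in the same cells, while Prkcd was found with Sst, Tac2 or Nts less often than independent markers would be. The largest association was between Crh and Tac2, with a mean log2 odds ratio of 4.33 ± 2.07 (SD, n = 9 samples). Of 84 Crh-positive cells, 50 were Tac2-positive, where independent markers would give 11.4. The mean log2 odds ratio was 4.20 ± 1.68 for Crh with Nts, 4.01 ± 2.23 for Tac2 with Nts, 3.36 ± 1.75 for Sst with Crh, 3.33 ± 1.01 for Sst with Nts and 3.22 ± 1.54 for Sst with Tac2. All 6 of these pairs lay above 0 in 9 of 9 samples. Prkcd and Sst shared 23 cells, where independence would give 62.7, and their mean log2 odds ratio was -2.45 ± 1.18, below 0 in 9 of 9 samples. Prkcd with Nts had a mean log2 odds ratio of -1.53 ± 1.05, also below 0 in all 9 samples. For each of these 8 pairs the exact two-sided sign-flip permutation test gave p = 0.00391, the smallest that 9 samples allow, and an adjusted p of 0.00488 over the 10 pairs. Prkcd with Tac2 had a mean log2 odds ratio of -1.35 ± 1.16, below 0 in 8 of 9 samples (exact permutation p = 0.00781, adjusted p = 0.00868). Prkcd and Crh showed no departure that passed the test, with a mean log2 odds ratio of -0.14 ± 1.06, above 0 in 7 of 9 samples (exact permutation p = 0.832, adjusted p = 0.832). This depended on the setting, since the co-expression of Prkcd and Crh was -0.93 at 3 counts per 10000, which passed (exact permutation adjusted p = 0.0469), and 0.32 at 1 count. When any cell with at least 1 count was taken as positive, the 3 negative pairs of Prkcd no longer passed, at log2 odds ratios of -0.30 with Sst, -0.13 with Tac2 and -0.38 with Nts.

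**Figure D1:**
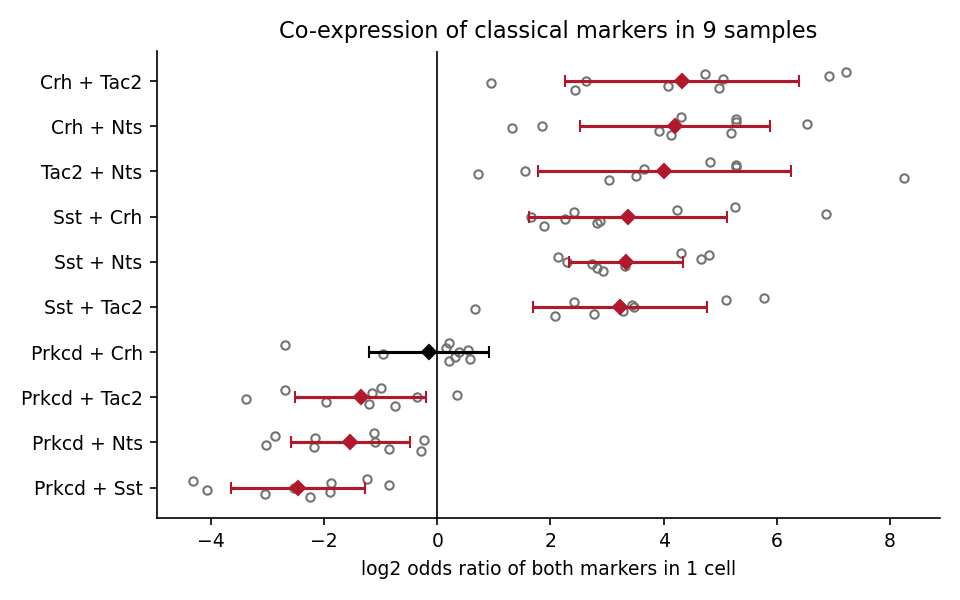
Log2 odds ratio of finding both markers in 1 cell, for the 10 pairs of classical markers. Open circles are the 9 samples, diamonds the mean and bars the SD, red where the adjusted p was under 0.05; the 6 pairs among Sst, Crh, Tac2 and Nts lie above 0 in every sample and Prkcd with Sst or Nts below 0 in every sample.

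At least 1 of the 5 classical markers was positive in 67.0% ± 8.43 of the inhibitory neurons (SD, n = 9), from 56.0% to 81.1% over samples. This left 266 cells with none of the 5, of which 58 were Nr2f2-positive and 33 Isl1-positive, 90 cells in all. With Calcrl, Drd1a, Drd2, Htr2a and Penk added, the 10 markers covered 94.4%. Among 29 transcription factor genes of forebrain inhibitory neurons, 4 were positive more often in the cells without a classical marker than in the others and 5 less often. Foxp1 rose from 14.9% ± 4.86 to 31.1% ± 10.9 of cells, Nr2f2 by 10.7 ± 7.24 percentage points to 21.6% ± 5.91, Pax6 from 6.61% ± 2.69 to 16.5% ± 3.17 and Rarb, a retinoic acid receptor, from 1.08% ± 1.12 to 6.02% ± 3.84. Tshz2 was positive in 22.7% ± 8.31 of the cells without a marker against 52.8% ± 6.55 of those with a marker. Sox5 was positive in 17.7% ± 4.09 against 32.5% ± 5.09, Bcl11b in 70.8% ± 5.97 against 83.2% ± 3.07, Tox in 2.04% ± 2.09 against 8.98% ± 3.72 and Meis2 in 67.2% ± 4.98 against 71.8% ± 4.19. The exact two-sided sign-flip permutation test gave an adjusted p of 0.0283 for each of these except Rarb, at 0.0378. Nr2f2 and Pax6 were higher in 9 of 9 samples and Foxp1 and Rarb in 8, while Tshz2 and Sox5 were lower in 9 and Bcl11b, Meis2 and Tox in 8. Isl1 was positive in 12.7% ± 5.06 of the cells without a marker, and the difference of 5.16 ± 7.31 percentage points did not pass (exact permutation p = 0.0703, adjusted p = 0.127). With a sample left out the number passing ranged from 0 to 4 higher and from 0 to 5 lower, and without the Mbp-positive cells it was 1 higher and 2 lower. With 8 samples the smallest p of the test is 0.00781. With positive cells at 1 count 0 and 0 passed by the exact permutation test (1 and 3 at an unadjusted p under 0.05; 6 samples, smallest p 0.0312), and Meis2 changed sign. With 10 markers 0 and 0 passed (0 and 0 unadjusted; 4 samples, smallest p 0.125), and Nr2f2, Foxp1 and Pax6 changed sign.

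The comparison of Prkcd with Sst cells asks what else separates the cells of the most common classical markers. Cells positive for Prkcd and not Sst (320 cells) had more Cartpt, the precursor of the CART peptide, than cells positive for Sst and not Prkcd (125 cells), with a log2 fold change of 6.35 ± 0.78 (SE, n = 9 samples, adjusted p = 9.77e-05). Penk was also higher in Prkcd cells (1.24 ± 0.21, adjusted p = 0.00124). The dynorphin precursor Pdyn was lower in Prkcd cells (-6.95 ± 0.49, adjusted p = 6.02e-07), at a mean of 19.6 CPM against 1678 CPM. So were Nts (-3.80 ± 0.66, adjusted p = 0.00182), Tac2 (-3.64 ± 0.65, adjusted p = 0.00229) and Crh (-2.68 ± 0.72, adjusted p = 0.0317). Of 10396 genes tested, 454 were higher and 421 lower in Prkcd cells at an adjusted p under 0.05, and with equal cell numbers in each class 249 were higher and 288 lower. Leaving each sample out in turn gave 348 to 421 higher and 324 to 397 lower, and DESeq2 1102 and 821.

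The genes named next moved the same way in every sample and, apart from Calcrl and Pvalb, had a mean of at least 10 CPM. Calcrl and Pvalb were added as passing members of gene lists. Toward Prkcd cells they included Papln, which encodes an extracellular matrix protein and had 0 counts in the Sst cells, and was at least 126-fold higher against a floor of 3 counts over the class. Calcrl and Pvalb, the gene of the calcium-binding protein parvalbumin, also had 0 counts in Sst cells and were at least 102-fold and 66.6-fold higher. C1ql2, a secreted synaptic protein of the C1q family, had 1 count in the Sst cells and a ratio of 687 (95% counting interval 123 to 27150). Igfbp2, an insulin-like growth factor binding protein, and the amino acid transporter Slc38a5 had 2 counts each there, with ratios of 345 (95.3 to 2849) and 285 (78.8 to 2358). The others were the nuclear receptor gene Rorb (log2 fold change 7.13 ± 0.87), secretagogin (Scgn, 6.91 ± 1.17), Nfkbiz, a regulator of NF-kB (6.86 ± 0.85), Atp10a (6.61 ± 0.87), the heparan sulfatase gene Sulf1 (6.36 ± 0.87), Bdnf, brain-derived neurotrophic factor (6.24 ± 0.88), and the collagen gene Col12a1 (6.18 ± 1.03). Toward Sst cells, Gulp1 had 3 counts in the Prkcd cells and a ratio of 324 (110 to 1579). Sema6d, a semaphorin, had a log2 fold change of -7.59 ± 0.80, Kctd15 -7.43 ± 1.09, the chemokine gene Cxcl14 -7.21 ± 0.98, Bend7 -6.93 ± 1.09, the serotonin receptor gene Htr2c -6.87 ± 0.62 and the adhesion gene Cntn4 -6.74 ± 0.87. Tmem90a was at -6.46 ± 0.62, Pcp4l1 at -5.98 ± 0.76, Camk2n1, an inhibitor of CaM kinase II, at -5.80 ± 0.38 and Rapgef3, a cAMP-activated exchange factor, at -5.73 ± 1.01. Each of these genes moved the same way in 9 of 9 samples, and their adjusted p ranged from 3.05e-07 (Camk2n1) to 0.0119 (Pvalb). Isl1 (-0.28 ± 0.77, adjusted p = 0.888) and Nr2f2 (2.37 ± 0.88, adjusted p = 0.128) did not pass.

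Among the gene lists, that of classical markers fell as a set in Prkcd cells, with 3 of 3 tested members lower (3 adjusted over the list alone), a camera adjusted p of 3.13e-05, and an adjusted p = 0.0482 with an estimated correlation. These 3 are Crh, Tac2 and Nts, which were found with Sst in the same cells above, so this call is not a separate result. Of 17 GABA and glycine receptor genes, 4 were lower and 13 did not pass (1 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.000376, and adjusted p = 0.0482 with an estimated correlation). They included the glycine receptor subunit Glra2 (-5.06 ± 0.75) and the GABA receptor subunit Gabra4 (-1.89 ± 0.26). Of 31 sodium, calcium and HCN channel genes, 2 were higher, 7 lower and 22 not passing (3 higher and 10 lower adjusted over the list alone), with a camera adjusted p of 0.000563 and an adjusted p = 0.0482 with an estimated correlation. The T-type calcium channel gene Cacna1i (-5.37 ± 1.40) and the cation channel gene Trpc5 (-3.53 ± 0.31) were among them. Of 44 axon guidance and adhesion genes, 10 were lower and 34 did not pass (7 higher and 11 lower adjusted over the list alone), Cntn4 and Sema6a (-4.88 ± 0.90) among them, with a camera adjusted p of 0.000340 and an adjusted p = 0.0433 with an estimated correlation. Of 8 general neuron genes, 6 were lower and 2 did not pass (7 lower adjusted over the list alone), among them the neurofilament gene Nefl (-2.63 ± 0.28) and the microtubule regulator Stmn2 (-2.39 ± 0.10), with a camera adjusted p of 1.27e-16 and an adjusted p = 0.000543 with an estimated correlation. The call on the 8 inhibitory neuron genes (1 higher, 3 lower, 4 not passing; 2 higher and 5 lower adjusted over the list alone) was lost with an estimated correlation, from a camera adjusted p of 0.0376 to an adjusted p = 0.136. There Dlx6as1 was lower (-2.22 ± 0.49). So was that on 3 astrocyte genes (2 lower; 1 higher and 2 lower adjusted over the list alone), from 0.0215 to an adjusted p = 0.0812 with an estimated correlation, with Aldoc (-3.59 ± 0.79) and the glutamate transporter gene Slc1a2 (-3.34 ± 0.48) lower. Random classes of the same cell numbers gave the call on classical markers in 3 of 10 draws, the opposite call in 1, and the other 6 lists were called in 0.

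The other lists were not called as sets between Prkcd and Sst cells, but some were under other settings. The immediate early genes were called upward in 7 of 15 other settings (camera adjusted p = 0.0400 with equal cell numbers) and the extended markers downward in 5 of 15 (0.000214 with equal cell numbers). Of 14 neuropeptide genes 4 were higher, 5 lower and 5 not passing (6 and 5 adjusted over the list alone; camera adjusted p = 0.313), and of 5 extended amygdala markers 2 were higher and 3 lower, as over the list alone (0.321). Of 13 neuropeptide receptor genes 1 was higher (Calcrl; 3 adjusted over the list alone; 0.371). Of 11 monoamine, acetylcholine, adenosine and cannabinoid receptor genes the cannabinoid receptor gene Cnr1 was higher (1.89 ± 0.26) and Htr2c lower (1 and 2 adjusted over the list alone; 0.140). Of 21 glutamate receptor genes Grm3 was higher (5.42 ± 1.12) and Gria3 lower (-1.29 ± 0.21), as over the list alone (0.409). Of 29 potassium channel genes 5 were lower (5 higher and 6 lower adjusted over the list alone; 0.313), including Kcnh1 (-4.03 ± 1.12) and Kcnc2 (-3.95 ± 0.97). Of 25 transcription factor genes 3 were higher and 6 lower (7 and 7 adjusted over the list alone; 0.371), including Sox5 (4.88 ± 0.72) and Tox (-5.52 ± 0.84). Of 15 immediate early genes 5 were higher and 1 lower (7 and 2 adjusted over the list alone; 0.0923), including Klf4 (3.30 ± 0.95) and Fosl2 (-2.44 ± 0.69). Of 9 striatal projection neuron genes 2 were higher and 1 lower (4 and 2 adjusted over the list alone; 0.515), including Foxo1 (3.68 ± 0.89) and Gpr6 (-4.74 ± 1.32). Of 4 intercalated cell genes Penk was higher and the neuregulin receptor gene Erbb4 lower (-4.40 ± 1.22), as over the list alone (0.730), and of 5 interneuron genes Pvalb alone passed, also over the list alone (0.707). Of 3 oligodendrocyte genes 1 was higher (1 adjusted over the list alone; 0.384). Of the lists with 1 tested gene, the endothelial gene Itm2a was higher (1.38 ± 0.29), also over the list alone. The excitatory, precursor and microglial ones did not pass over all genes (1 lower, 0 and 1 higher adjusted over the list alone), and no ependymal gene was tested. Mean folds and the camera direction differed in sign for the inhibitory neuron, glutamate receptor, transcription factor and striatal lists.

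Of the 53 genes named here that passed between Prkcd and Sst cells, 44 did so with each sample left out in turn. The highest adjusted p with a sample left out was 0.0990 for Kcnh1 (without sample 1), 0.0510 for Kcnc2 (without sample 2), 0.0770 for Cacna1i (without sample 9), 0.103 for Klf4 (without sample 4), 0.105 for Fosl2 (without sample 7), 0.123 for Gpr6 (without sample 2), 0.0862 for Erbb4 (without sample 2) and 0.0828 for Crh (without sample 8), and Pvalb was tested with 8 of the 9 left out.

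**Figure D2:**
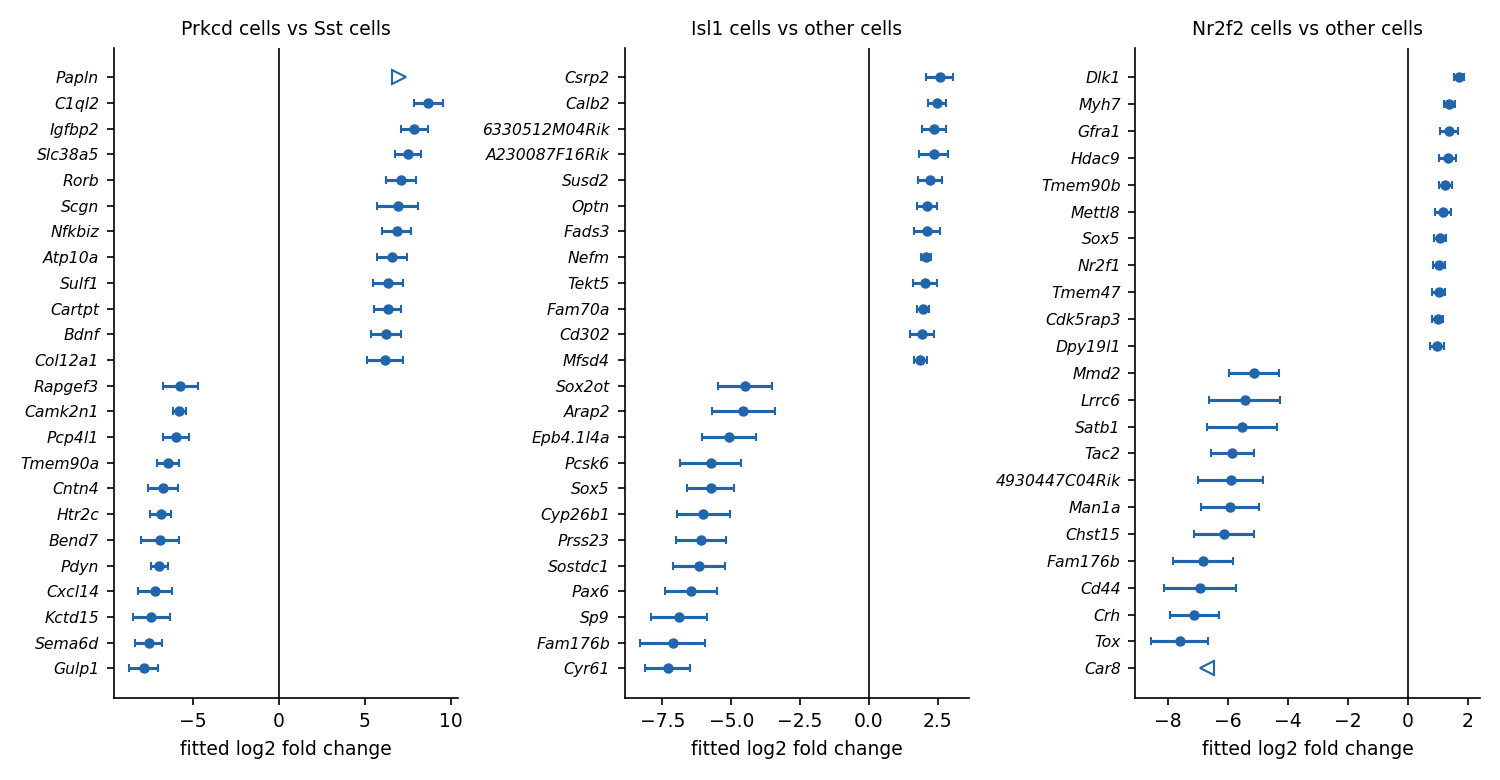
Fitted log2 fold change of up to 12 genes on each side in the 3 comparisons, among genes that moved the same way in every sample, with bars of 1 SE over 9 samples. Triangles mark Papln and Car8, which had 0 counts in a class and are drawn at the bound of at least 126-fold and 103-fold.

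Isl1 encodes a LIM homeodomain transcription factor of the developing striatum, and the comparison asks which genes go with it. Isl1-positive cells (76 cells) had less Prkcd than the other 734 inhibitory neurons, with a log2 fold change of -2.92 ± 0.42 (SE, n = 9 samples, adjusted p = 0.00115). They also had less Sst (-3.77 ± 0.82, adjusted p = 0.0162), less Nr2f2 (-4.81 ± 1.04, adjusted p = 0.0160) and less Penk (-2.45 ± 0.30, adjusted p = 0.000427). They had more of the calretinin gene Calb2 (2.48 ± 0.34, adjusted p = 0.000943) and of the neurofilament gene Nefm (2.07 ± 0.19, adjusted p = 3.62e-05). Of 11168 genes tested, 189 were higher and 352 lower, at a median log2 fold change over all genes of -0.34. Median-of-ratios scaling gave 253 higher and 312 lower, and equal cell numbers in each class gave 79 higher and 73 lower with a median of 0.06. Without the sample block 261 were higher and 242 lower at a median of -0.0433. Leaving out a sample gave 142 to 181 higher and 252 to 309 lower, and DESeq2 537 and 1619.

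Among genes at a mean of at least 10 CPM that moved the same way in every sample, those higher in Isl1 cells included Csrp2, a LIM-domain protein gene (2.57 ± 0.50), Calb2, 6330512M04Rik (2.37 ± 0.43), A230087F16Rik (2.36 ± 0.52), Susd2 (2.23 ± 0.43), the autophagy receptor gene Optn (2.11 ± 0.35), the fatty acid desaturase gene Fads3 (2.11 ± 0.48), Nefm, Tekt5 (2.03 ± 0.44), Fam70a (1.97 ± 0.23), Cd302 (1.93 ± 0.44) and Mfsd4 (1.86 ± 0.24). Among the genes lower in Isl1 cells, Cyr61, which encodes a matrix-associated protein, had 3 counts in the Isl1 cells and a ratio of 122 (95% counting interval 41.6 to 591). The transcription factor genes Sp9 (-6.89 ± 1.01), Pax6 (-6.46 ± 0.96) and Sox5 (-5.75 ± 0.85) were lower, as were Fam176b (-7.13 ± 1.18) and Sostdc1, an antagonist of BMP and Wnt signals (-6.17 ± 0.93). The serine protease gene Prss23 (-6.10 ± 0.91), Cyp26b1, whose enzyme breaks down retinoic acid (-6.02 ± 0.96), the proprotein convertase gene Pcsk6 (-5.75 ± 1.11), Epb4.1l4a (-5.09 ± 0.98), Arap2 (-4.56 ± 1.15) and the noncoding RNA Sox2ot (-4.51 ± 0.98) were lower too. Each moved the same way in 9 of 9 samples, with adjusted p from 3.62e-05 (Nefm) to 0.0349 (Arap2). Crh (-2.82 ± 1.11, adjusted p = 0.170), Tac2 (0.31 ± 0.74, adjusted p = 0.838) and Nts (-0.46 ± 0.59, adjusted p = 0.690) did not pass.

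The list of general neuron genes rose in Isl1 cells and held with an estimated correlation. There 3 of 8 genes were higher and 5 did not pass (4 higher and 1 lower adjusted over the list alone), with Nefl at 1.52 ± 0.15 and Stmn2 at 1.51 ± 0.10, a camera adjusted p of 5.70e-10 and an adjusted p = 0.00241 with an estimated correlation. The other 8 list calls were lost with an estimated correlation. Of 14 immediate early genes, 4 were lower and 10 did not pass (7 lower adjusted over the list alone), including Npas4 (-3.71 ± 0.77) and Fos (-2.19 ± 0.49), with a camera adjusted p of 7.14e-06 and an adjusted p = 0.0707 with an estimated correlation. Of 9 extended amygdala markers, 4 were lower, including Calcrl (-5.01 ± 1.31), and 5 did not pass (5 lower adjusted over the list alone; camera adjusted p = 0.000548, and adjusted p = 0.0707 with an estimated correlation). Of the 5 classical markers, Sst and Prkcd were lower and 3 did not pass (3 lower adjusted over the list alone; camera adjusted p = 0.00707, and adjusted p = 0.170 with an estimated correlation). Of 28 transcription factor genes, 2 were higher, 7 lower and 19 not passing (2 and 10 adjusted over the list alone; camera adjusted p = 0.0167, and adjusted p = 0.108 with an estimated correlation). Dlx1 had 0 counts in Isl1 cells and was at least 28.1-fold lower. Of 12 striatal projection neuron genes, 4 were lower and 8 did not pass (5 lower adjusted over the list alone; camera adjusted p = 0.0167, and adjusted p = 0.170 with an estimated correlation). Gpr6 had 1 count in Isl1 cells and a ratio of 275 (49.3 to 10860), and Foxo1 had a log2 fold change of -6.01 ± 1.22. Of 16 neuropeptide genes, 1 was higher, 3 were lower, with Cartpt at -2.77 ± 0.61, and 12 did not pass (2 and 8 adjusted over the list alone; camera adjusted p = 0.0259, and adjusted p = 0.108 with an estimated correlation). Of 5 interneuron genes Calb2 was higher and 4 did not pass (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0247, and adjusted p = 0.108 with an estimated correlation). Of 4 astrocyte genes Aldoc was higher (1.73 ± 0.26) and 3 did not pass (1 adjusted over the list alone; camera adjusted p = 0.0247, and adjusted p = 0.180 with an estimated correlation). Random classes of the same cell numbers gave the same call in 7 of 10 draws for the extended markers, in 5 for the classical markers and for the neuropeptides, in 2 for the striatal and in 1 for the immediate early genes, and called the interneuron genes in the opposite direction in 2.

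In the lists not called as sets, few genes passed between Isl1 cells and the others. Of 22 glutamate receptor genes 2 were higher and 2 lower (2 and 3 adjusted over the list alone; camera adjusted p = 0.707), including Grin3a (1.39 ± 0.30) and Grm5 (-0.76 ± 0.19). Of 32 sodium, calcium and HCN channel genes 2 were higher and 1 lower (3 and 2 adjusted over the list alone; 0.750), including the T-type calcium channel gene Cacna1g (1.57 ± 0.34) and Cacng3 (adjusted p = 0.00343). Of 30 potassium channel genes Kcna1 (-1.50 ± 0.33) and Kcnip2 (-1.30 ± 0.33) were lower, as over the list alone (0.898). Of 18 GABA and glycine receptor genes Gabra2 was lower (-0.66 ± 0.14), as over the list alone (0.352). Of 52 axon guidance and adhesion genes Cdh13 was higher (1.19 ± 0.18) and 2 were lower, including Pcdh19 (-1.25 ± 0.27; 1 and 5 adjusted over the list alone; 0.960). Of 21 neuropeptide receptor genes Calcrl was lower (1 higher and 3 lower adjusted over the list alone; 0.929), and of 19 monoamine, acetylcholine, adenosine and cannabinoid receptor genes 0 passed, also over the list alone (0.999). Of 8 inhibitory neuron genes Gad2 was higher (0.38 ± 0.09) and Dlx1 lower (1 and 4 adjusted over the list alone; 0.256). Of 8 intercalated cell genes Penk was lower (2 adjusted over the list alone; 0.128). Of 3 oligodendrocyte genes 1 was lower (1 adjusted over the list alone; 0.256). The excitatory, precursor, microglial, endothelial and ependymal lists had 1 tested gene each, which did not pass, also over the list alone. Mean folds were below 0 where camera pointed up for the monoamine, glutamate, GABA, sodium channel and axon guidance lists.

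Of the 48 genes named here that passed between Isl1 cells and the others, 41 did so with each sample left out in turn. The highest adjusted p with a sample left out was 0.0687 for Fads3 (without sample 4), 0.0545 for Cd302 (without sample 6), 0.0769 for Arap2 (without sample 6), 0.0949 for Calcrl (without sample 3), 0.0772 for Grm5 (without sample 8), 0.0831 for Kcnip2 (without sample 2) and 0.0556 for Gad2 (without sample 1). Without the Mbp-positive cells, 95 genes were higher and 201 lower.

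Nr2f2 encodes the nuclear receptor COUP-TFII, and the comparison asks which genes go with it. Nr2f2-positive cells (116 cells) had less Crh than the other 694 inhibitory neurons, with a log2 fold change of -7.12 ± 0.82 (SE, n = 9 samples, adjusted p = 0.000846). They also had less Tac2 (-5.85 ± 0.73, adjusted p = 0.00110), Sst (-4.68 ± 0.37, adjusted p = 1.87e-05), Nts (-4.70 ± 1.09, adjusted p = 0.0425) and Isl1 (-5.82 ± 1.05, adjusted p = 0.0120). Prkcd did not pass (-0.40 ± 0.27, adjusted p = 0.549), at 291 ± 220 CPM against 327 ± 97.1 CPM (mean ± SD). Nr2f2 cells had more Dlk1, a Notch ligand relative (1.72 ± 0.17, adjusted p = 0.000171), and more of the kappa opioid receptor gene Oprk1 (2.24 ± 0.47, adjusted p = 0.0312). Of 11007 genes tested, 44 were higher and 141 lower, and equal cell numbers in each class gave 5 higher and 17 lower. With a sample left out the numbers ranged from 20 to 32 and from 63 to 109, and DESeq2 gave 201 and 1097. The median log2 fold change over all genes was -0.24, and -0.0374 with equal cell numbers. Random classes of the same cell numbers had a mean median of -0.20. The smaller number of cells in the Nr2f2 class could therefore account for part of this shift in that model.

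Among genes at a mean of at least 10 CPM that moved the same way in every sample, those higher in Nr2f2 cells included Dlk1, the myosin gene Myh7 (1.40 ± 0.18), the GDNF receptor gene Gfra1 (1.39 ± 0.30), the histone deacetylase gene Hdac9 (1.34 ± 0.29), Tmem90b (1.26 ± 0.22), Mettl8 (1.18 ± 0.27), Sox5 (1.09 ± 0.19), Nr2f1 (1.04 ± 0.21), Tmem47 (1.03 ± 0.20), Cdk5rap3 (1.01 ± 0.18) and Dpy19l1 (0.99 ± 0.23). Nr2f1 is the close relative of Nr2f2, and how reads matching both were counted is not given in the sources used here. Toward the other cells, Car8, a gene of the carbonic anhydrase family, had 0 counts in Nr2f2 cells and was at least 103-fold lower. The transcription factor gene Tox had 2 counts there and a ratio of 155 (95% counting interval 42.9 to 1282). The hyaluronan receptor gene Cd44 (-6.93 ± 1.21), Fam176b (-6.82, adjusted p = 0.00343), the chondroitin sulfotransferase gene Chst15 (-6.13 ± 0.99), the mannosidase gene Man1a (-5.92 ± 0.97), 4930447C04Rik (-5.91 ± 1.08), the chromatin organizer gene Satb1 (-5.53 ± 1.15), Lrrc6 (-5.43 ± 1.18) and Mmd2 (-5.12 ± 0.83) were also lower. Each moved the same way in 9 of 9 samples, with adjusted p from 0.000171 (Dlk1) to 0.0414 (Dpy19l1).

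Lists of peptide and projection neuron genes fell as sets in Nr2f2 cells and held with an estimated correlation. Several of the lists share genes, so their calls are not separate results. The extended list holds all classical markers, and Crh, Tac2, Sst and Nts, lower above, encode peptides. Drd1a belongs to the extended, striatal, intercalated and monoamine lists. Of 5 classical markers, 4 were lower and 1 did not pass, as over the list alone, where 4 were lower adjusted over the list alone (camera adjusted p = 1.29e-18, and adjusted p = 0.000389 with an estimated correlation). Of 9 extended markers 5 were lower and 4 did not pass (5 lower adjusted over the list alone; camera adjusted p = 2.47e-16, and adjusted p = 0.000389 with an estimated correlation). Of 16 neuropeptide genes 7 were lower and 9 did not pass (11 lower adjusted over the list alone; camera adjusted p = 3.58e-18, and adjusted p = 0.00346 with an estimated correlation). Of 13 striatal projection neuron genes 2 were lower and 11 did not pass (4 lower adjusted over the list alone; camera adjusted p = 3.32e-05, and adjusted p = 0.00680 with an estimated correlation). The dopamine receptor gene Drd1a had 2 counts in Nr2f2 cells and a ratio of 81.0 (22.4 to 670), and Ppp1r1b, which encodes DARPP-32, was lower (-1.83 ± 0.34). Of 9 intercalated cell genes Drd1a was lower and 8 did not pass (5 lower adjusted over the list alone; camera adjusted p = 0.00422, and adjusted p = 0.0361 with an estimated correlation), and with equal cell numbers the camera adjusted p was 0.177. Another 5 calls were lost with an estimated correlation. Of 19 monoamine, acetylcholine, adenosine and cannabinoid receptor genes Drd1a and Adra2a, with 0 counts in Nr2f2 cells and at least 35.4-fold lower, fell and 17 did not pass (2 lower adjusted over the list alone; camera adjusted p = 0.0349, and adjusted p = 0.264 with an estimated correlation). Of 30 potassium channel genes Kcnh1 (-5.90 ± 1.23) and Kcnd2 (-1.42 ± 0.31) were lower (5 adjusted over the list alone; camera adjusted p = 0.0349, and adjusted p = 0.0783 with an estimated correlation). Of 49 axon guidance and adhesion genes Sema6a, with 2 counts in Nr2f2 cells and a ratio of 129 (35.8 to 1069), and Lypd1 (-1.27 ± 0.13) were lower, as over the list alone (2 lower adjusted over the list alone; camera adjusted p = 0.0349, and adjusted p = 0.0858 with an estimated correlation). Of 7 interneuron genes the neuropeptide Y gene Npy (-5.39 ± 0.83) and 6330527O06Rik (-0.93 ± 0.16) were lower (3 adjusted over the list alone; camera adjusted p = 0.0349, and adjusted p = 0.0858 with an estimated correlation). The list of 16 immediate early genes was called higher (camera adjusted p = 0.0491, and adjusted p = 0.306 with an estimated correlation), although Fosl2 was lower (-4.32 ± 1.01), 15 did not pass (1 higher and 1 lower adjusted over the list alone) and the mean fold was below 0. Random classes of the same cell numbers gave the same call in 2 of 10 draws for the intercalated, monoamine and interneuron lists, in 1 for the classical, extended and neuropeptide lists and in 0 for the others, with 0 opposite calls.

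The remaining lists were not called as sets between Nr2f2 cells and the others. Of 30 transcription factor genes 2 were higher and 5 lower (3 and 11 adjusted over the list alone; camera adjusted p = 0.145), Tox and Isl1 among the lower. Of 17 neuropeptide receptor genes Oprk1 was higher and Vipr1 lower (-4.54 ± 1.03; 1 and 2 adjusted over the list alone; 0.881). Of 22 glutamate receptor genes 1 was higher (2 higher and 1 lower adjusted over the list alone; 0.513), and of 32 sodium, calcium and HCN channel genes Cacna2d1 alone (-1.11 ± 0.22; 1 higher and 3 lower adjusted over the list alone; 0.796). Of 8 inhibitory neuron genes Gad1 was higher (0.45 ± 0.10; 1 higher and 2 lower adjusted over the list alone; 0.796). In the lists of 18 GABA and glycine receptor genes (0.338), 8 general neuron genes (0.796), 3 astrocyte genes (0.796) and 3 oligodendrocyte genes (0.796) 0 genes passed over all genes. Adjusted over the list alone there were 1 lower, 2 higher with 5 lower, 1 lower and 0. The excitatory, precursor, microglial, endothelial and ependymal lists had 1 tested gene each, with 0, 0, 1, 0 and 1 lower adjusted over the list alone. Mean folds were below 0 where camera pointed up for the neuropeptide receptor and glutamate receptor lists.

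Of the 40 genes named here that passed between Nr2f2 cells and the others, 20 did so with each sample left out in turn, and the highest adjusted p with a sample left out was 0.110 (Fosl2, without sample 5). Drd1a lost its call without sample 5 alone (adjusted p = 0.0663). The calls ended with any of several samples left out for Gfra1, Hdac9, Mettl8, Nr2f1, Tmem47, Dpy19l1, Car8, Satb1, Lrrc6, Vipr1, Oprk1, Adra2a, Kcnh1, Kcnd2, Cacna2d1, Fosl2, Gad1 and Nts, and Npy was tested with 6 of the 9 left out. Summed per date field, 0 genes were higher and 3 lower by edgeR, with 1218 at an unadjusted p under 0.05, and DESeq2 was not run on these sums.

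Clusters were made from the same counts and are described without tests. The neurons fell into 10 clusters of 171, 161, 92, 81, 80, 74, 64, 44, 36 and 7 cells, numbered by size. Cluster 1 was 97.1% Prkcd-positive and led by Pvalb, the collagen gene Col27a1, Cartpt and Tmcc3. Of its 171 cells, 19 were positive for Pvalb, 17 for Col27a1, 146 for Cartpt and 94 for Tmcc3. Its Cartpt was at 2524 ± 687 CPM (SD, n = 9 samples), a ratio of 5.98 to the next cluster. Cluster 2 was led by Slc41a3, Aldoc, Amn and the synaptotagmin gene Syt4, and its Aldoc was at 382 ± 170 CPM (n = 9, ratio 3.25). Cluster 3 was led by Ccdc88c and the G protein gene Gng7 (194 ± 38.5 CPM, n = 9, ratio 1.56). In cluster 4 Nr2f2 alone met the rule (230 ± 64.6 CPM, n = 9, ratio 2.73), and in cluster 5 the amyloid precursor relative Aplp2 (1258 ± 94.7 CPM, n = 9, ratio 1.42). Cluster 6 was led by Ctxn3, the cholecystokinin gene Cck, the guanylate cyclase gene Gucy1a3 and the serotonin receptor gene Htr1f, with Cck at 523 ± 240 CPM (n = 6, ratio 16.8). Cluster 7 was led by Galnt14, Camk2n1 and Glra2, with Camk2n1 at 470 ± 109 CPM (n = 6, ratio 3.89). Cluster 8 was led by the peptide receptor gene Vipr2, Nts and Expi, with Nts at 3350 ± 1265 CPM (n = 5, ratio 15.1). Cluster 9 was led by the serotonin receptor gene Htr1a, Eml1 and Slc35f1, with Htr1a at 67.0 ± 32.1 CPM (n = 4, ratio 3.73). Some leading genes were positive in a small part of their cluster, with Slc41a3 in 20 cells, Htr1f in 16, Galnt14 in 15, Htr1a in 8 and Eml1 in 7. Cluster 10 reached 5 cells in no sample, and the genes that the rule picked there, Edn1, Gchfr, Iqcf5 and Pmch, were each positive in 1 cell. Chat and the choline transporter gene Slc5a7, chosen after their values were seen, were positive in all 7 of its cells.

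The classical markers covered the clusters unequally. At least 1 was positive in 100% of clusters 7 and 8, 97.1% of cluster 1, 86.3% of cluster 5, 81.5% of cluster 3, 57.1% of cluster 10, 54.0% of cluster 2, 27.2% of cluster 4, 22.2% of cluster 9 and 6.76% of cluster 6. Clusters 2, 6 and 4 held 27.8%, 25.9% and 22.2% of the cells without a classical marker. Of the 14 striatal projection neuron genes in the table, 8 were highest in cluster 6, among them Adcy5, Adora2a, Drd1a, Drd2, Pde10a, Rarb and Sh3rf2. The top 10 genes by fold of cluster 2 held 7 oligodendrocyte genes, which came mainly from 2 cells positive for at least 4 genes of that list. The clusters were left unnamed.

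**Figure D3:**
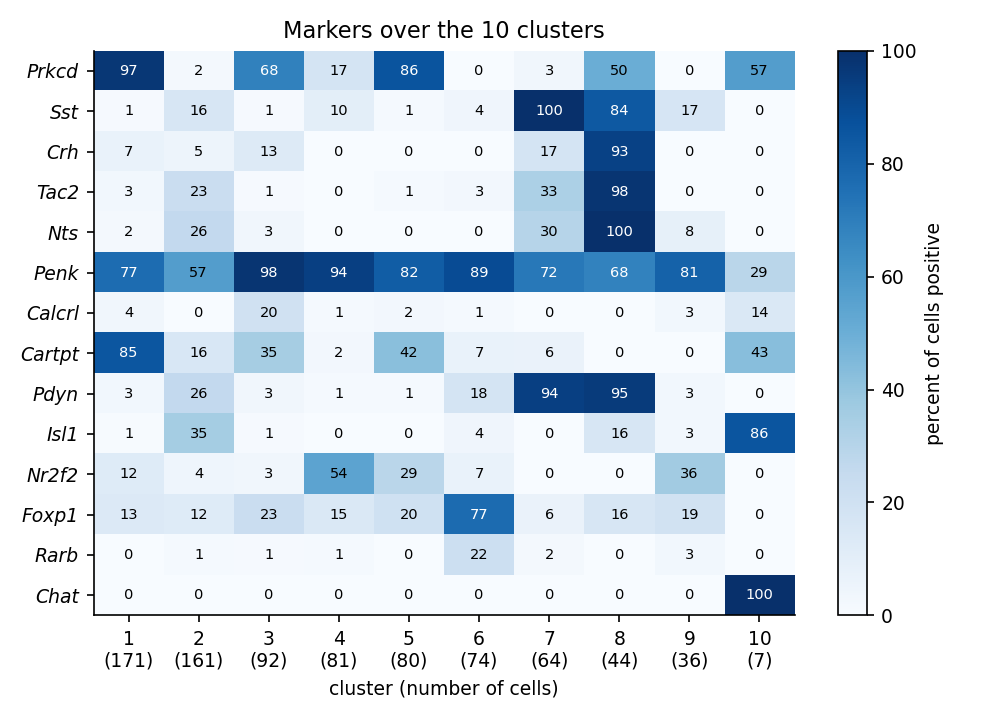
Percent of cells positive for 14 genes in each of the 10 clusters, with the number of cells under each cluster number. Crh, Tac2 and Nts are shared most by cluster 8, and Foxp1 and Rarb by cluster 6, where the classical markers covered 6.76% of cells.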

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

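Of the tests in this part only the swaps of class labels were planned, and those on the median fold in Isl1 cells, on Mbp and on counts per spike-in count were chosen after the result was seen. With class labels swapped within samples, edgeR gave at most 0 genes in the other 49 of 50 arrangements for each comparison. The real Prkcd, Isl1 and Nr2f2 classes gave 875, 541 and 185 genes, so 1 arrangement of 50 reached the real number. A swap turns real class differences into spread within classes, so few genes would pass in the other arrangements whenever the classes differ. These swaps therefore cannot show how many genes pass between classes drawn by chance. The 10 draws of random classes, chosen after the data were seen, gave at most 0, 1 and 0 genes by edgeR.

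Mbp was positive in 210 inhibitory neurons. Whole oligodendrocyte material in the well would bring other genes of that cell type, but only 7.62% of the 210 cells were positive for another of 8 oligodendrocyte genes. Against 2 cells positive for at least 4 of these genes (Mbp at 11375 CPM, and 74.6 CPM in the other neurons), free RNA or carry-over that brings this Mbp would put Mobp at 66.0 CPM, where 0.797 CPM was found. Over the 8 genes the median was 1.42% of the expected level and at most 5.90% in a sample, which argues against oligodendrocyte RNA of that make-up, although Cnp was at 25.6% and Mal at 221%. Low transcription of Mbp in the neurons themselves, or debris of another make-up, could remain, and neither was tested.

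The median log2 fold change over all genes was -0.34 in Isl1 cells. Random classes of the same cell numbers had a mean median of -0.38, so the smaller number of cells in the Isl1 class could account for it in that model. It also depended on the model, at -0.0433 on the same genes and cells without the sample block and 0.11 by DESeq2 over genes without a filter. Median-of-ratios scaling gave -0.29, so the TMM scaling does not explain it. Leaving out the 2 cells with many oligodendrocyte genes gave -0.33, but so few cells could hardly move the median. That value therefore decides nothing about oligodendrocyte material. Leaving out all Mbp-positive cells gave -0.37. With equal cell numbers the median was 0.06.

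Isl1 cells had more gene counts per spike-in count than the other neurons, 9.72 ± 2.64 against 6.90 ± 1.13 (SD, n = 9), a mean log2 difference of 0.46 ± 0.22, above 0 in 9 of 9 samples (exact permutation p = 0.00391, adjusted p = 0.0156 over 4 comparisons). Cholinergic cells among them do not account for it, since the difference was 0.40 without the Chat-positive cells. With classes from thinned counts the difference was 0.45, so an easier call of Isl1 from more counts alone does not account for it. Whether the counts hold PCR copies is not known, so thinning may not equalise the RNA captured per cell. An easier call of Isl1 in cells with more captured RNA therefore remains open. The difference could come from larger cells, which was not tested.

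Spike-in RNA made up 12.1% of all counts. Among 184 sets of per-sample values, 26 had a sample far from the other 8 by the Dixon ratio, where chance would give 9.2 for normally distributed values. Genes with few counts in a class and shares near 0 need not be so distributed, so an excess cannot be read from these numbers. Sample 9 was the one set apart in 8 sets and sample 1 in 7. The median counts per cell were 227570 in sample 5, with the next at 152952. The share of Tac2-positive cells was 29.5% in sample 1 (next 15.1%), of Isl1-positive cells 17.9% in sample 1 (next 11.1%), of Drd2-positive cells 8.33% in sample 9 (next 3.66%) and of Htr2a-positive cells 1.19% in sample 9 (next 0). The log2 odds ratio of Prkcd with Crh was -2.69 in sample 8, with the nearest other at -0.95.

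Between Prkcd and Sst cells the log2 difference of Scgn was 0.0938 in sample 7 (nearest other 3.97), of Bdnf 1.24 in sample 3 (4.38), of Gria3 0.42 in sample 9 (-0.98) and of Kcnc2 3.79 in sample 9 (-2.20). Between Isl1 cells and the others that of Nefm was 3.57 in sample 7 (2.24), of Fam176b -0.76 in sample 1 (-4.91), of Sp9 -1.90 in sample 1 (-5.31), of Sostdc1 -1.73 in sample 2 (-4.72), of Fos -9.93 in sample 9 (-5.03), of Foxo1 0.88 in sample 1 (-3.08) and of Nts -8.08 in sample 4 (-2.83). Between Nr2f2 cells and the others it was -3.58 for Tox in sample 9 (-5.21), -1.82 for Crh in sample 4 (-6.65), -0.16 for Cd44 in sample 1 (-4.27), -2.22 for Fam176b in sample 2 (-4.51) and -0.24 for Chst15 in sample 9 (-4.73). It was -0.62 for 4930447C04Rik in sample 1 (-3.80), -0.14 for Vipr1 in sample 8 (-2.43), 0.76 for Kcnh1 in sample 9 (-3.08) and 1.83 for Isl1 in sample 5 (-4.88).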

How the results depend on the processing

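Equal cell numbers, sums per animal number or date field, and leaving out Mbp-positive cells were chosen after the data were seen. Over 4794 values under other settings, the named genes kept their direction and side of the threshold in 1774 cases, ended their call in 489, reversed in 12 and passed newly in 3, and with a sample left out in 1124, 187, 3 and 0. These counts pool settings that changed little with others. Per date field 45 named genes kept their result and 10 ended their call between Prkcd and Sst cells. For Isl1 cells these were 16 and 34, and for Nr2f2 cells 2 and 39. Per animal number they were 44 and 11, 20 and 30, and 7 and 34 in the same order. With equal cell numbers they were 37 and 4, 21 and 19, and 9 and 17. Lists that were called kept their call in 329 cases, lost it in 82 and reversed in 2. The cause was not tested unless a number of samples is given.

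For Prkcd against Sst cells, genes higher and lower were 1102 and 821 by DESeq2, 124 and 92 with positive cells at 1 count, 217 and 192 without Mbp-positive cells (8 samples) and 249 higher with equal cell numbers. Sums per animal number gave 250 higher and per date field 239. With a sample left out they ranged from 348 to 421 and from 324 to 397. Isl1 turned from -0.28 to 0.12 with at least 10 cells per class and ranged from -0.70 to 0.12 with a sample left out, above 0 without sample 9. Both values above 0 are from the same fit, since only sample 9 had under 10 cells in a class.

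For Isl1 cells, DESeq2 gave 537 higher and 1619 lower, positive cells at 1 count 358 higher, and sums per animal number 88 and 58 and per date field 42 and 41. Without Mbp-positive cells there were 95 and 201, and with equal cell numbers 79 and 73. At 3 counts per 10000 there were 1 and 3 and at 10 cells per class 0 and 3 by edgeR (421 and 885 at an unadjusted p under 0.05), with 2 samples left in each. With a sample left out they ranged from 142 to 181 and from 252 to 309. At 3 counts per 10000 Fads3 turned to -1.81, Cacna1g to -0.21 and Gad2 to -0.11. Crh turned to 0.15 at 10 cells per class, and Isl1 cells vs other cells: Tac2 ranged from -0.0574 to 0.75 with a sample left out, below 0 without sample 2 or 4. Nts turned to 0.50 at 10 cells per class, 0.49 without the block, 0.56 at 3 counts per 10000, 0.63 per animal number and 0.37 per date field.

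For Nr2f2 cells, 20 were higher without a filter, and 201 higher and 1097 lower by DESeq2. Positive cells at 1 count gave 71 higher, at 3 counts per 10000 3 and 9 (6 samples), and at 10 cells per class 83 lower (8 samples). Without Mbp-positive cells there were 14 and 53 (8 samples), per animal number 5 and 11, per date field 0 and 3 by edgeR (1218 at an unadjusted p under 0.05) and with equal cell numbers 5 and 17. With a sample left out they ranged from 20 to 32 and from 63 to 109. The monoamine receptor list turned upward with equal cell numbers (camera adjusted p = 0.867) and the immediate early genes downward at 3 counts per 10000 (0.299). The value of Nr2f2 cells vs other cells: Prkcd turned to 0.0599 with equal cell numbers and 0.0471 with positive cells at 1 count.

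Positive cells at 1 count brought the log2 odds ratio of Prkcd to -0.30 with Sst, 0.32 with Crh, -0.13 with Tac2 and -0.38 with Nts. The co-expression of Prkcd and Crh was -0.93 at 3 counts per 10000 (exact permutation adjusted p = 0.0469) and 0.15 with thinned counts. With a sample left out Prkcd with Crh ranged from -0.23 to 0.18, with Sst from -2.65 to -2.22, with Tac2 from -1.56 to -1.10 and with Nts from -1.70 to -1.35. The share of cells with a classical marker was 90.2% at 1 count, 58.1% at 3 per 10000, 94.4% with 10 markers and from 65.2% to 68.3% with a sample left out. Transcription factors higher and lower in cells without a marker were 0 and 0 at 1 count (6 samples; 1 and 3 at an unadjusted permutation p under 0.05), 1 higher with thinned counts, 1 and 2 without Mbp-positive cells, 0 and 0 with 10 markers (4 samples; 0 and 0) and from 0 to 4 and 0 to 5 with a sample left out. At 1 count the difference turned to -4.25 for Isl1 and 0.55 for Meis2. With 10 markers the share of Nr2f2 without minus with a classical marker turned to -12.5, the share of Foxp1 without minus with a classical marker to -1.23 and the share of Pax6 without minus with a classical marker to -4.19.

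Some lists that were not called at first were called by camera under other settings. Between Prkcd and Sst cells the immediate early genes were called upward in 7 of 15 settings and with 1 of 9 samples left out (adjusted p from 0.00342 to 0.0400). That sample was 9, and the setting of at least 10 cells per class is the same fit, so these calls are not separate. The extended markers were called downward in 5 of 15 and with 1 of 9 left out (0.000214 to 0.0446), and the monoamine receptor list in 4 of 15 and with 1 of 9 left out (0.000786 to 0.0339). Random classes called the extended markers downward in 2 of 10 draws and upward in 1, and the other 2 lists in 0. Per date field the neuropeptides (1.30e-06) and interneuron genes (1.22e-10) were also called downward. For Isl1 cells the intercalated genes were called downward at 3 counts per 10000 (0.0190) and per date field (0.00693), and the oligodendrocyte genes per date field (0.00316). For Nr2f2 cells the transcription factors were called downward in 3 of 15 settings (0.00980 to 0.0275) and the oligodendrocyte genes at 3 counts per 10000 (0.0335).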

Other observations

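The tests between date fields in this part were chosen after the data were seen. Cluster 8 brought 3 classical markers together, with Nts positive in 44 of its 44 cells, Tac2 in 97.7% and Crh in 93.2%. It held 48.8% of all Crh-positive cells. Cluster 2 held 75% of the Isl1-positive cells, and 35.4% of its cells were Isl1-positive, 26.1% Nts-positive and 23.0% Tac2-positive. Nr2f2 was positive in 54.3% of cluster 4, 36.1% of cluster 9 and 28.8% of cluster 5, and in 0 of the 64 cells of cluster 7 and the 44 of cluster 8. In cluster 6 Foxp1 was positive in 77.0% and Rarb in 21.6% of cells, and it held 72.7% of all Rarb-positive cells. In cluster 10, 6 of the 7 cells with Chat were Isl1-positive.

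Against the 10 clusters at resolution 1, the adjusted Rand index was 0.785 at resolution 0.5 (8 clusters), 0.610 at resolution 2 (15 clusters) and 0.755 with cells of 20000 counts or more, and it was 0.726 between clusters of 2 random parts of the counts.

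Between the 3 date fields (n = 3 samples each), the share of Nr2f2-positive cells was 11.1%, 12.9% and 19.4% (exact permutation p = 0.0179), of cluster 6 3.21%, 14.0% and 10.3% (p = 0.0107), of cluster 3 13.6%, 7.54% and 13.1% (p = 0.0250) and of cells with a classical marker 76.7%, 62.2% and 61.9% (p = 0.0321). The adjusted permutation p was 0.169 for each over 21 measures, where 280 arrangements allow a smallest p of 0.00357.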
